A study of Homo sapiens with 4 samples.

How the data were processed

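Chromatin immunoprecipitation with sequencing (ChIP-seq) was used to locate the vitamin D receptor (VDR) on DNA in primary prostate epithelial cells. VDR is a nuclear receptor that binds DNA and is activated by 1,25-dihydroxyvitamin D3 (calcitriol), the hormonally active form of vitamin D. Per the labels' protocols, cells isolated from benign prostate tissue were exposed to 50 nM calcitriol or to the ethanol vehicle for 2 hr. The chromatin was cross-linked with formaldehyde and sheared, and VDR-bound fragments were collected with a rabbit polyclonal antibody. The series holds 4 samples, which are an input library and a VDR ChIP library for each condition. All came from one cell preparation, so each condition has 1 ChIP library and no replicate.

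The peak positions used here are those the authors called, with 1 deposited list for each ChIP library. Peaks were called with MACS2 on genome build hg19 from reads converted with bcl2fastq 1.8.4, per the submitters' processing notes. The aligner, the MACS2 version, the calling threshold and the use of the input libraries as controls are not given in the sources used here. Each list has 4 columns without a header, the chromosome, start, end and name of each peak, all in base pairs of hg19. Neither list holds a height, score, fold or p-value per peak, so the only size measure was the peak width. Peak names ran consecutively in both lists. Read depth is unknown for every library, and a deeper or better enriched library can yield more and wider peaks at equal binding. Starts are given here as 1-based positions.

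A vitamin D peak was called shared when it overlapped an ethanol peak by at least 1 bp, and the reverse. Overlap was counted with numpy 2.4.6 and pandas 2.3.3 under Python 3.11.15, and was checked peak by peak against bedtools 2.31.1. Chance overlap came from 1000 random placements of the ethanol peaks on their own chromosomes, between the first and the last peak of the 2 lists. A second set of 1000 draws moved the ethanol list as a whole along each chromosome by a random offset, which keeps its internal spacing. For spacing within 1 Mb, peaks were also placed at random inside their own 1 Mb window. Widths of shared and unshared peaks were compared as medians with a two-sided permutation test of 100000 resamples. Widths at sites matched one to one were compared with an exact two-sided sign test. Shares carry exact (Clopper-Pearson) 95% intervals from scipy 1.17.1, which cover counting error only. Because each condition has 1 library, every p-value describes the peaks of these lists and none tests the conditions. The sign test compares the 2 libraries over sites, which are not replicates, so its p-value is no test of the hormone. The 22 tests of the report and of the additional observations were taken as 1 family for Benjamini-Hochberg adjustment (statsmodels 0.14.6). Raw p-values are printed. Permutation p-values of 0.001 became 0.0015, that of 0.0072 for chromosomes became 0.0089, and those of 0.013, 0.018 and 0.037 became 0.015, 0.02 and 0.039. The test of pairs 5 to 20 kb apart (permutation p = 0.14) was the only 1 of the 22 above 0.05 after adjustment. The stratified permutation test was tested on simulated data with the 4784 vitamin D peaks. It called 5% of 40 simulations in which overlap depended on the width decile alone, and 90% of 10 simulations with an added regional effect. The first rate follows from permuting within the same deciles, and width effects inside a decile were not simulated. The regional effect was shared by peaks with gaps of at most 20 kb, the same pairs that the test counts.

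The comparisons of peak number, overlap, width, motifs and genes were fixed before the data were examined, with their tests and a set of alternatives. Several could not be carried out. The peaks are on hg19 and the gene table at hand is for GRCh38.p14, so its coordinates were not used and no peak was assigned to a gene. The 19 gene lists and 24 sequence motifs chosen in advance, which included the direct repeat bound by VDR with its partner RXR, were not used here for the same reason, as no hg19 sequence or annotation was at hand. Rankings by peak score were replaced by rankings by width after the lists were seen. Named regions were the 12 widest vitamin D peaks without an ethanol peak, the 5 widest shared peaks and the 5 widest ethanol peaks without a vitamin D peak. Every group of at least 5 vitamin D peaks separated by gaps of at most 20 kb was named as well. Named regions and values per chromosome were limited to the 22 autosomes. The analyses of groups, of distance to ethanol peaks and of differences between chromosomes were added after the lists were seen. Of the alternatives fixed in advance, those run were a 50% reciprocal overlap (for overlap and for width) and midpoints within 1 kb (for overlap). Width minimums, the widest peaks only, other gaps and distances, permutation of whole groups of peaks, midpoints for width and autosomes only were added after the lists were seen. So were the shift of the whole ethanol list, the width test among ethanol peaks and the sign test at matched sites.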

Results

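VDR binding sites were mapped in primary prostate epithelial cells after 2 hr with 50 nM calcitriol or with ethanol, to find where the receptor sits on DNA with and without added hormone. Each condition was represented by 1 ChIP library, and the values below therefore carry no replicate error. The ethanol list held 1255 peaks that covered 421 kb of hg19. The vitamin D list held 4784 peaks that covered 1351 kb. Peaks were narrow in both lists, with a median width of 269 bp in ethanol (quartiles 165.5 and 461.5 bp) and 222 bp in vitamin D (quartiles 154 and 344 bp). The narrowest peak was 100 bp in ethanol and 109 bp in vitamin D, and 37 and 191 peaks had exactly these widths. No 2 peaks of the same list overlapped.

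The vitamin D library had 3.81 times as many peaks as the ethanol library and 3.21 times the covered length. Among peaks at least as wide as the median vitamin D peak, the counts were 2396 with vitamin D and 739 with ethanol, a ratio of 3.24. Nearly the whole ethanol set recurred with vitamin D. Of the 1255 ethanol peaks, 1213 overlapped a vitamin D peak (96.7%, exact 95% interval 95.5 to 97.6%). Of the 4784 vitamin D peaks, 1205 overlapped an ethanol peak (25.2%, interval 24.0 to 26.4%), which left 3579 peaks in the vitamin D list alone and 42 in the ethanol list alone. With the vitamin D list cut to its widest 1255 peaks, as many as the ethanol list holds, 67.4% of them overlapped an ethanol peak and 68.1% of the ethanol peaks overlapped one of them. Random placement of the ethanol peaks gave a mean of 1.36 overlapping peaks and at most 6 (permutation p = 0.001, the smallest that 1000 draws can give). Moving the ethanol list as a whole along each chromosome gave a mean of 1.47. With 1 library per condition, the difference in peak number has no test, and differences in depth or enrichment between the libraries are not separated from it.

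Vitamin D peaks shared with the ethanol library were wider than those found with vitamin D alone. Shared vitamin D peaks had a median width of 446 bp (quartiles 302 and 607 bp, 1205 peaks). Peaks of the vitamin D list alone had a median of 190 bp (quartiles 141 and 264.5 bp, 3579 peaks). The difference of 256 bp exceeded every one of 100000 permutations of the peaks (two-sided permutation p = 1e-05, the smallest these can give). The share of vitamin D peaks with an ethanol counterpart was 1.88% (interval 0.863 to 3.54%) in the narrowest decile, where the median width was 111 bp. It was 11.3% (8.60 to 14.5%) in the fifth decile, 63.2% (58.7 to 67.5%) in the ninth and 87.7% (84.4 to 90.5%) in the widest, where the median was 660.5 bp. In the widest decile, 59 of 478 peaks had no ethanol counterpart. Across the list, 91 of the 3579 peaks without an ethanol counterpart were wider than 500 bp, against 493 of the 1205 shared peaks.

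**Figure D1:**
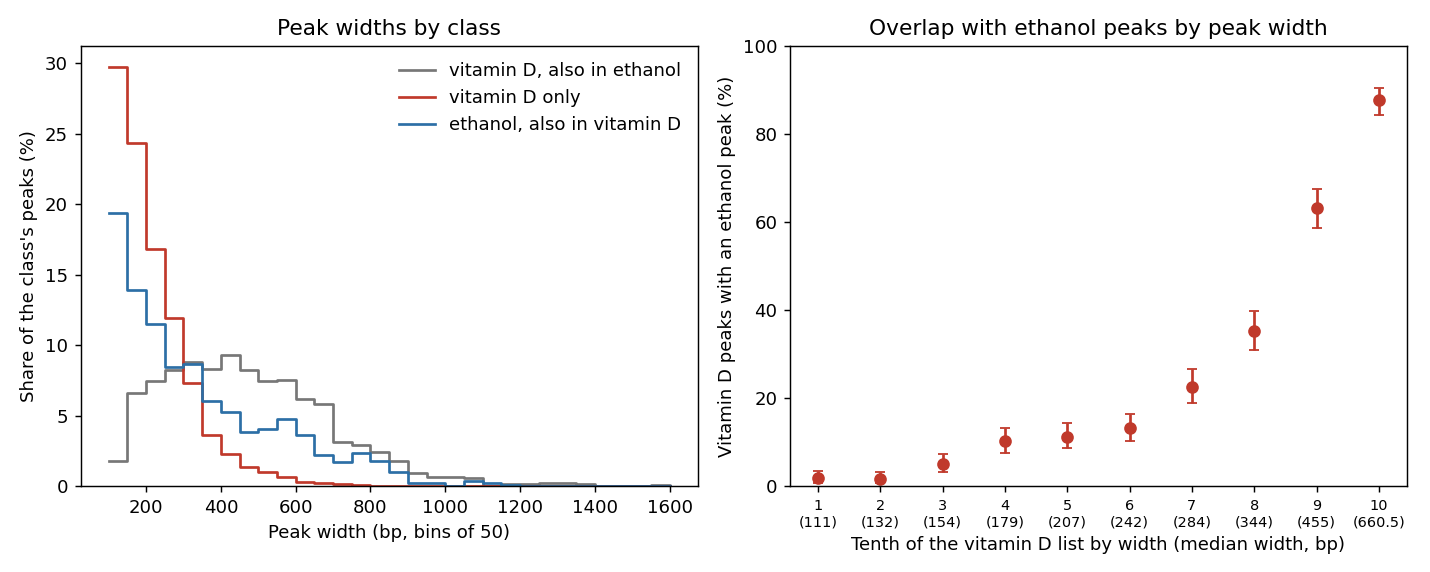
The left panel plots the share of peaks (%) in bins of 50 bp of peak width for shared vitamin D peaks, vitamin D peaks without an ethanol peak, and ethanol peaks with a vitamin D peak. The right panel plots, for each width decile of the vitamin D list, the share of peaks (%) that overlap an ethanol peak with exact 95% intervals, which lies at 1.88% in the narrowest decile and 87.7% in the widest.

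At the same sites, peaks were wider in the vitamin D library than in the ethanol library. The sites come from 1 library of each condition and are not replicates. A difference in depth or enrichment between the libraries is not separated from this difference in width. Neither is a difference in how widths were called, as the narrowest peak was 100 bp in ethanol and 109 bp in vitamin D. Among 1194 sites where 1 ethanol peak met 1 vitamin D peak, the vitamin D peak was the wider in 1002, the narrower in 187 and equal in 5 (83.9% wider, interval 81.7 to 86.0%, exact two-sided sign test p = 4.5e-135). The median width at these sites was 445 bp with vitamin D and 277 bp with ethanol, and the median ratio was 1.37 (quartiles 1.09 and 1.95). The ethanol peak lay wholly inside the vitamin D peak at 774 of the 1194 sites (64.8%). In 9 cases a vitamin D peak overlapped 2 ethanol peaks, and in 1 case an ethanol peak overlapped 2 vitamin D peaks.

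The widest autosomal peak shared by both libraries lay on chromosome 21 (9825458 to 9827011, 1554 bp), where the vitamin D peak overlapped 2 ethanol peaks of 1282 bp in all. No filter for regions of nonspecific signal was applied here, so a wide shared peak need not mark VDR binding. A peak of 1380 bp on chromosome 1 (43147075 to 43148454) met an ethanol peak of 877 bp. On chromosome 2, a peak of 1372 bp (219523449 to 219524820) overlapped 2 ethanol peaks totalling 1306 bp, and another of 1310 bp (27850768 to 27852077) overlapped 2 totalling 636 bp. A peak of 1333 bp on chromosome 19 (42387806 to 42389138) met an ethanol peak of 1088 bp.

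The widest peaks of the vitamin D list without an ethanol counterpart were spread over 8 chromosomes. The first of them measured 1034 bp on chromosome 1 (17559607 to 17560640), and the nearest ethanol peak was 179 kb away. It was followed by a peak of 992 bp on chromosome 11 (119567033 to 119568024), 46.7 kb from an ethanol peak. The peak of 869 bp on chromosome 7 (143028284 to 143029152) was the closest of the set to an ethanol peak, at 2.32 kb. Peaks of 799 bp on chromosome 15 (71587418 to 71588216) and 794 bp on chromosome 1 (197744850 to 197745643) were 977 kb and 2526 kb from the nearest ethanol peak. Of the remaining 7, which measured 700 to 758 bp, 3 were on chromosome 1 (40265657 to 40266414, 16126461 to 16127173 and 209830538 to 209831241). The other 4 were on chromosome 12 (123372822 to 123373537), chromosome 9 (72120744 to 72121455), chromosome 16 (87887086 to 87887796) and chromosome 17 (80245862 to 80246561).

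The 42 ethanol peaks without a vitamin D counterpart were narrow, with a median of 122.5 bp (quartiles 108.75 and 187 bp) against 277 bp for the 1213 shared ethanol peaks (two-sided permutation p = 0.0015). The widest on the autosomes were 2 peaks on chromosome 17, of 335 bp (8076579 to 8076913) and 322 bp (4890480 to 4890801). They were followed by peaks of 261 bp on chromosome 21 (19061293 to 19061553), 229 bp on chromosome 1 (6135841 to 6136069) and 211 bp on chromosome 19 (56165101 to 56165311). Of the 42, 3 lay within 1 kb of a vitamin D peak and 9 within 20 kb.

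Vitamin D peaks were grouped along the chromosomes. A neighbour within 20 kb was found for 1197 of the 4784 peaks (25.0%), against 7.01% after random placement and 12.6% after placement within the peaks' own 1 Mb windows (permutation p = 0.001 for each, the smallest that 1000 draws can give). Within 50 kb the shares were 38.4%, 16.4% and 26.3%. Some of this came from peaks in immediate proximity. With peaks less than 5 kb apart taken as 1 region, 583 of 4415 regions had a neighbour within 20 kb (13.2%). The share was 6.47% after random placement and 10.8% after placement within windows (permutation p = 0.001 for each). Placed regions were not merged again, so their shares also count gaps under 5 kb, which merging removed from the observed regions. The observed and placed shares are therefore not like measures. There were 103 groups of 3 or more peaks, of which 47 held no ethanol peak.

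The most populated group lay on chromosome 10 (74010572 to 74058748), where 12 vitamin D peaks over 48.2 kb included 2 with an ethanol counterpart. A further group of 5 lay just beyond it (74079630 to 74094968) and had no ethanol peak. Another region of chromosome 10 (5589895 to 5653139) held 9 vitamin D peaks over 63.2 kb and no ethanol peak. A region of chromosome 5 (180611200 to 180688827) held 7 vitamin D peaks, 3 of them shared. A region of chromosome 20 (52724284 to 52757885) held 6 vitamin D peaks, 3 of them shared. There the shared pairs measured 628, 577 and 283 bp with vitamin D and 433, 314 and 139 bp with ethanol. A region of chromosome 6 (28948674 to 28984720) also held 6 vitamin D peaks, and 4 of them were shared. Groups of 5 without an ethanol peak were found on chromosome 1 (209827265 to 209847368) and at 2 places on chromosome 12 (3563675 to 3567446 and 125401485 to 125424629). Groups of 5 with 1 shared peak were found on chromosome 17 (41534374 to 41561525) and chromosome 20 (30145274 to 30160985 and 49038612 to 49057681).

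**Figure D2:**
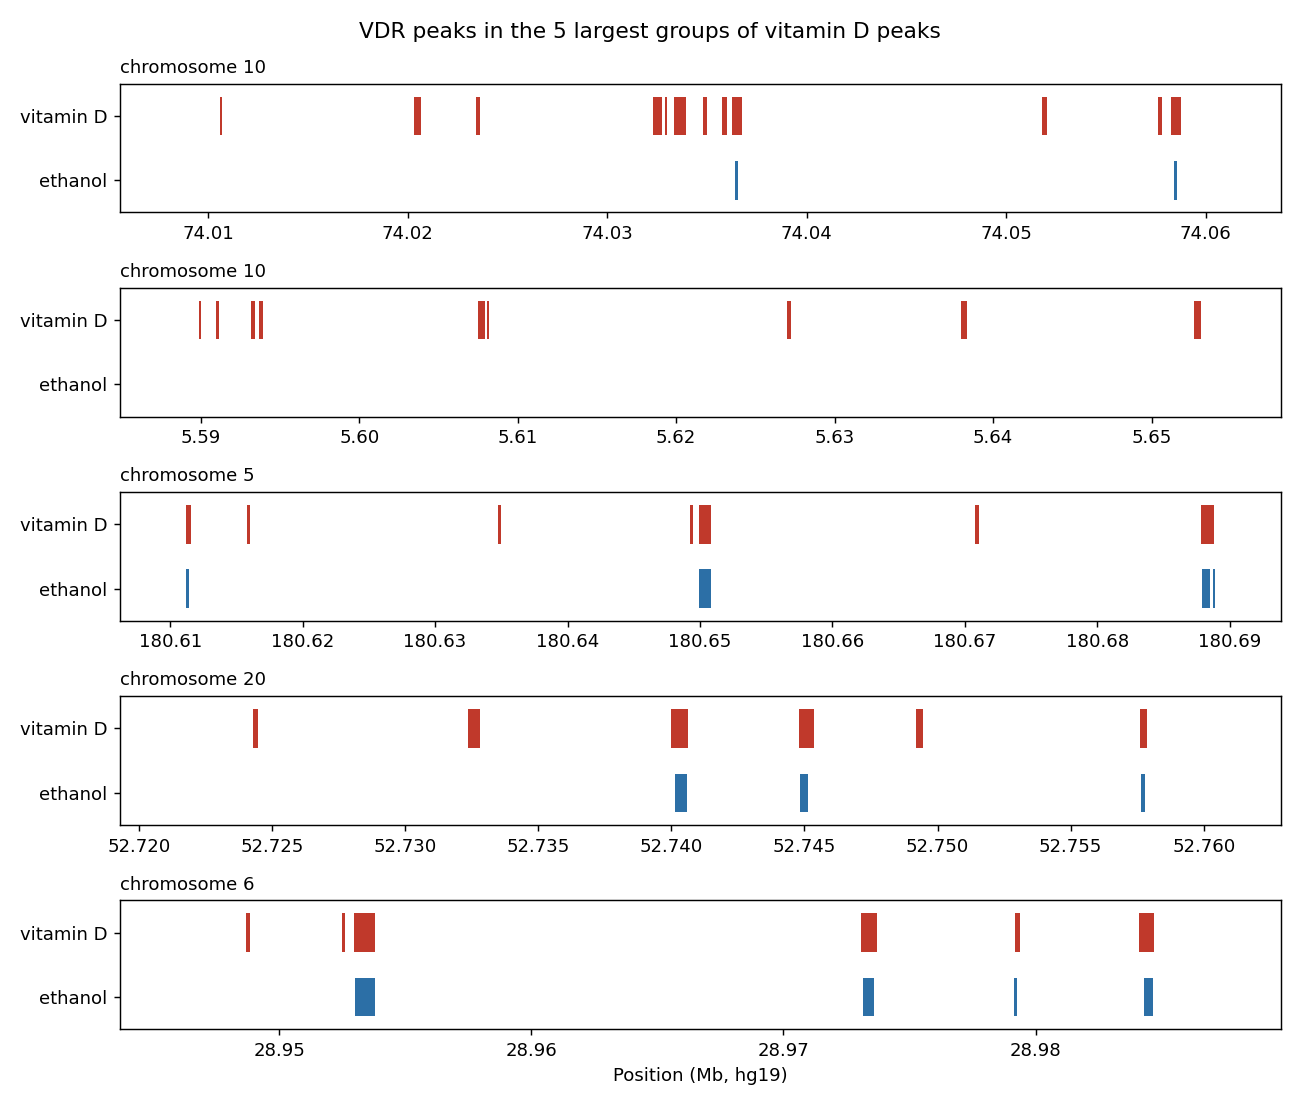
Each panel maps 1 of the 5 most populated groups of vitamin D peaks on hg19, with position in Mb on the horizontal axis, vitamin D peaks as red bars in the upper row and ethanol peaks as blue bars in the lower row, drawn to scale. The region on chromosome 10 with 9 vitamin D peaks has no ethanol peak, and the region on chromosome 20 has 6 and 3.

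Peaks found with vitamin D alone lay closer to ethanol peaks than after shifts of the ethanol list or placement within windows. Of the 1255 ethanol peaks, 1213 overlapped a vitamin D peak. Nearness to an ethanol peak is thus nearly nearness to a shared vitamin D peak. It is not separated from the grouping of vitamin D peaks. Of the 3579 peaks of the vitamin D list alone, 656 were within 100 kb of an ethanol peak (18.3%, interval 17.1 to 19.6%). The share was 8.20% when the ethanol list was moved along the chromosomes, a 2.24-fold difference, and 13.7% when the vitamin D peaks were placed within their own 1 Mb windows (permutation p = 0.001 for each). Within 20 kb the shares were 6.99%, 1.82% and 3.42%, and within 500 kb 47.3%, 30.8% and 45.0%. At distances of 5 to 20 kb, which leaves out peaks beside an ethanol peak, the observed share was 3.86% against 2.19% after placement within windows (permutation p = 0.001). Placement within windows moved each peak independently, although vitamin D peaks were grouped. Its spread may therefore be too small and its p-values too low. The shift of the ethanol list, which keeps the spacing within each list but not between them, was not run for 5 to 20 kb. Status was also permuted within width deciles with all positions kept. Adjacent vitamin D peaks within 20 kb then had equal status in 475 of 681 pairs, against a permuted mean of 427.4. Peaks found with vitamin D alone thus adjoined shared peaks less often than permuted. The median distance to the nearest ethanol peak was 546 kb (quartiles 161 and 1412 kb).

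Peak density differed between autosomes in both libraries. Densities were taken over the span from the first to the last peak of the 2 lists on each chromosome, not over its full length. Over the 22 autosomes there were 1.70 vitamin D peaks and 0.443 ethanol peaks per Mb. Chromosome 19, which is rich in genes, had 3.25 vitamin D and 1.01 ethanol peaks per Mb, and chromosome 17 had 3.08 and 0.908. By this measure chromosome 4 had the lowest densities, at 1.02 and 0.179 per Mb, and gene-poor chromosome 13 had 1.06 and 0.224. The spans used were 189.9 Mb for chromosome 4 and 93.9 Mb for chromosome 13, and the order over full lengths was not examined. The share of vitamin D peaks with an ethanol counterpart was 33.7% on chromosome 16 (69 of 205, interval 27.2 to 40.6%) and 16.6% on chromosome 4 (32 of 193, interval 11.6 to 22.6%), the highest and lowest of the 22. The shares differed between chromosomes by more than permuted peaks did (permutation p = 0.0072 with 100000 permutations), also when peaks were permuted within width deciles (permutation p = 0.018). Both tests treat peaks as independent, although peaks close to each other tended to have the same status. With groups of peaks within 20 kb permuted as whole blocks, the permutation p was 0.013, and within width deciles 0.037.

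**Figure D3:**
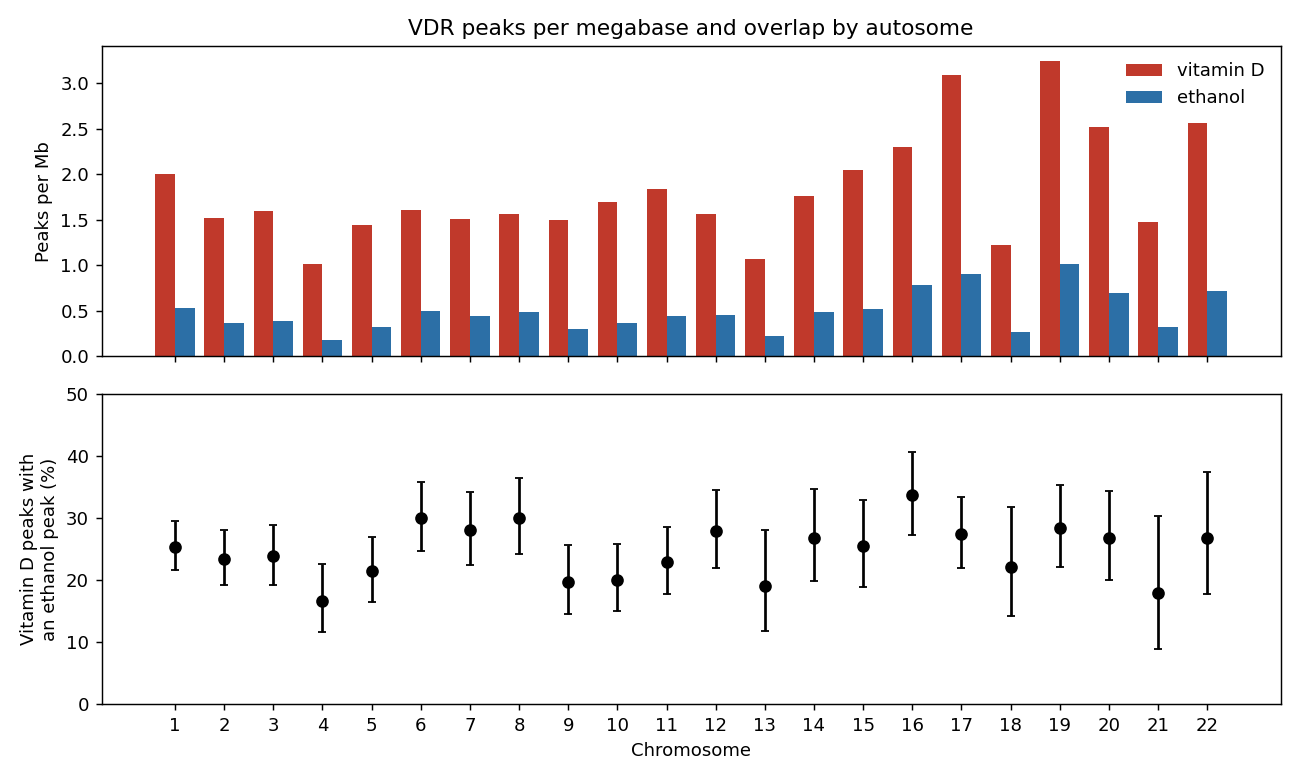
The upper panel plots peaks per Mb on each autosome for vitamin D (red) and ethanol (blue), with 3.25 and 1.01 on chromosome 19 and 1.02 and 0.179 on chromosome 4. Each density is per Mb of the span from the first to the last peak. The lower panel plots the share of vitamin D peaks (%) that overlap an ethanol peak, with exact 95% intervals.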

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

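Alternatives other than the 50% reciprocal overlap and the 1 kb midpoint rule were chosen after the lists were seen. Of 43 alternative values, none reversed and 9 moved (by over 1.5-fold for a count, or outside the interval for a share). The others stayed within these limits or, where tested, on the same side of the 0.05 threshold. Counts and covered lengths have no direction to reverse. At a minimum of 109 bp, the narrowest vitamin D width, the number and covered length of vitamin D peaks could not change. Sizes of tested values depended on the distance and on the null. With gaps of up to 10, 20 and 50 kb, 18.9, 25.0 and 38.4% of vitamin D peaks had a neighbour, against 7.10, 12.6 and 26.3% after placement within 1 Mb windows. With peaks under 5 kb apart merged, 13.2% of 4415 regions had a neighbour within 20 kb, against 10.8% after placement within windows. The placed regions were not merged again, so the 10.8% also counts gaps under 5 kb and is not a like measure. Vitamin D only peaks within 20, 100 and 500 kb of an ethanol peak were 3.83, 2.24 and 1.54 times as frequent as after shifts of the ethanol list, but 2.04, 1.34 and 1.05 times as frequent as after placement within 1 Mb windows. At 500 kb the last comparison was 47.3% against 45.0%. None of these values is separated from the grouping of vitamin D peaks. With peaks at least as wide as the median vitamin D peak, 739 ethanol and 2396 vitamin D peaks were left, and the ratio of peak numbers was 3.24. Of these, 97.8% of the ethanol and 30.1% of the vitamin D peaks overlapped a peak left in the other list. Wide vitamin D peaks over a narrower ethanol peak then counted as unshared. Against the full ethanol list, the shared part was 13.2% in the sixth width decile and 87.7% in the widest. A common minimum of 109 bp left 1180 ethanol peaks, and the shared part of the vitamin D list was 23.9%, with the same limit. A reciprocal overlap of 50% lowered the shared part to 71.8% of ethanol and 18.8% of vitamin D peaks. A peak that is less than 50% as wide as its partner fails this rule at any position. At matched sites, the upper quartile of the width ratio of vitamin D over ethanol was 1.95. How many pairs were lost for this reason was not counted. With the vitamin D list reduced to its widest 1255 peaks, 68.1% of ethanol peaks and 67.4% of vitamin D peaks were shared. The near-complete recovery of the ethanol set thus includes narrower vitamin D peaks. Of 23 alternatives planned, 3 were run. Those on peak score, repeats, motifs and genes were not run, because the lists hold no score and no hg19 sequence or annotation was at hand. No depth is known, which leaves sites bound below the calling threshold in ethanol unseen.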

Other observations

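The 2 permutation tests of neighbours up to 20 kb and 5 to 20 kb apart were specified before their results were seen, and the other tests in this part after. Peaks near each other tended to have the same status. Of 681 adjacent pairs of vitamin D peaks separated by at most 20 kb, 475 were equal (69.8%), with 53 pairs both shared and 422 pairs both without an ethanol peak. Permuting the status over all peaks gave 424.3 equal pairs on average. Permuting it within width deciles gave 427.4, or 62.8% (permutation p = 0.0001, the smallest that 10000 permutations can give), and finer strata of width gave 62.7%. Stratifying by width thus moved the expected number little, and similar widths of neighbours do not account for the excess that remained. A candidate explanation is that single bound regions were called in pieces. The excess lay in close pairs, with 74.3% of 369 pairs under 5 kb apart equal against 63.7% after permutation. The 312 pairs 5 to 20 kb apart gave 64.4% against 61.7% (permutation p = 0.14), and the contrast between close and distant pairs was larger than permuted (permutation p = 0.0065). A hormone response shared by nearby sites stays open, as do local differences in recovery between the libraries.

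Groups of vitamin D peaks without any ethanol overlap were more numerous than width alone would give. Of 103 groups of 3 or more, 47 had no peak that overlapped an ethanol peak, against a mean of 33.9 after permutation within width deciles (permutation p = 0.0003). This count was examined after the groups were seen and includes groups of closely spaced peaks. It rests on the same peaks and status as the test of adjacent pairs and is not independent of that test.

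The larger number of peaks with vitamin D could come from hormone-dependent binding or from a uniformly lower sensitivity of the ethanol library. It could also include calls near the threshold in the vitamin D list, which no score is at hand to test. Of the 3579 peaks of the vitamin D list alone, 1064 (29.7%) were in the width bin of 100 to 150 bp. Lower sensitivity would lose narrow sites first and keep nearly every wide one. Overlap did rise steeply with width, from 1.88% in the narrowest decile to 87.7% in the widest, and matched sites were narrower in ethanol at 1002 of 1194 sites. The 59 peaks of the widest decile without an ethanol peak, led by the site of 1034 bp on chromosome 1, fall short of a full recovery. They do not exclude lower sensitivity, because width is a coarse stand-in for enrichment and the spread between repeat libraries is unknown, so the explanations cannot be told apart for the list as a whole.

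The 42 ethanol peaks without a vitamin D counterpart may be calls near the threshold or sites that lost binding with hormone. Their narrow width (median 122.5 bp against 277 bp, two-sided permutation p = 0.0015) is the observation that raised the first explanation and gives it no independent support. No peak score or replicate is at hand for another test, so these explanations cannot be told apart.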
